A study of Mus musculus with 6 samples.

How the data were processed

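Reduced representation bisulfite sequencing was carried out on mouse bone marrow cells (C57BL/6J, all samples labelled male) at 3 times of culture in medium with Flt3L, a cytokine that drives the growth of dendritic cells from marrow. Per the labels' protocols, aliquots of DNA were cut separately with MspI or TaqI, pooled, joined to adapters with methylated cytosines, treated with bisulfite and amplified. The assay therefore reads cytosines near the cut sites of these enzymes, and bisulfite leaves methylated cytosines as they are while it converts unmethylated ones. Per the submitters' processing notes, the reads were handled with Bismark and Bowtie2 on the mm9 build. Versions, trimming, treatment of duplicate reads and strand handling are not given in the sources used here. The labels give no molecular identifiers, so intervals and detection limits cover counting error only.

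The deposited table gives 3 values per sample for each of 652716 cytosines: the methylated fraction, the count of unmethylated reads and the count of methylated reads. At each cytosine with reads in a sample, the deposited fraction equalled methylated reads divided by all reads, up to rounding. The deposited read counts carried no other scaling. The smallest sum of reads over the 2 samples of any group was 10, so the authors' minimum of 10 applied to groups and not to samples. Only 14004 cytosines had at least 10 reads in each of the 6 samples, and 640616 had at least 1. The table holds 641910 autosomal cytosines, 9898 on the X chromosome, 27 on unplaced Y sequence, 0 on the assembled Y chromosome and 31 on the mitochondrial sequence. Only 65 neighbouring pairs lay 1 bp apart, so the table does not list both strands of most CpG sites.

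Samples were grouped by their titles and by the days in culture given in the labels. The labels do not say whether the samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Replicates were counted as separate samples, as the labels list them. Between the 2 samples of a group, the chi-square per degree of freedom over regions against read-counting noise was 1.80 at day 0, 1.73 at day 4 and 1.89 at day 7, a measure that PCR duplicates would also raise.

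A region was a run of at least 3 cytosines of the table whose neighbours lay at most 100 bp apart. There were 69246 such regions, of which 56834 had at least 10 reads summed over the region in each sample and 56105 also had at least 1 methylated and 1 unmethylated read over the samples. The median region held 5 cytosines over 104 bp. Applying the minimum of 10 reads to the region sum and not to each cytosine is 1 reading of the rule fixed beforehand, which named the minimum without saying where it applied. The other reading was run as an alternative chosen after the data were seen. Cytosines were tested one by one only where each sample had at least 10 reads.

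Differences were tested with edgeR 4.0.16 in R 4.3.3, by a negative binomial model of methylated and unmethylated counts with a term for each sample and a methylation term for each group. All 6 samples entered 1 model, dispersion was estimated without a trend, and each contrast was tested by a likelihood ratio test with Benjamini-Hochberg adjustment over all units tested. A region or cytosine was called at an adjusted p below 0.05 with a difference of group mean levels of at least 20 percentage points. The level of a region is its methylated reads as a percent of all its reads. Named regions were, per contrast, the 10 largest rises and the 10 largest falls among called regions with at least 20 reads in each sample and with both samples of a group beyond both of the other. Because X regions filled most places among the rises, the same rule was also applied to autosomes alone, which was decided after the data were seen. No region was assigned to a gene. Gene positions on mm9 were not used here, and coordinates of another build were not converted. For that reason the planned promoter tests, gene-list tests and marker loci were not run, and regions carry mm9 coordinates only.

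Tests were fixed before the data were examined, as were most alternatives: other minimum differences, an edgeR quasi-likelihood test, limma 3.58.1 on log ratios with a pseudocount of 0.5, Fisher's exact test on pooled reads, other coverage limits, other region rules, autosomes alone, only the 2 groups compared, and each sample left out in turn. The edgeR test was checked on simulated counts at the depths of the real samples with 200 regions changed. At a planted difference of 20 points it recovered 6%, 16% and 14% of changed regions for day 4 against day 0, day 7 against day 4 and day 7 against day 0. At 50 points it recovered 96%, 82% and 76%. Since a call needs an observed difference of at least 20 points, recovery at a planted 20 points is held down by that rule. False calls made up 2.94%, 4.72% and 4.85% of calls in this simulation. It set the same spread between samples for every region, not estimated from the data, and drew the changed regions at random. Regions with a level above 50% were only lowered and the others only raised. Rises from above 50% were therefore not simulated. Real regions may vary more unevenly and real calls gathered on the X chromosome, so the real share of false calls may be larger. Mean levels were compared by exact two-sided permutation tests, whose smallest p for 2 samples against 2 is 0.333. Intervals are 95% Wilson intervals, and the detection limit at a level of 0% is 3 reads of the total. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.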

Results

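DNA methylation was measured in bone marrow cells before culture (day 0, replicates 2 and 3), after 4 days (replicates 1 and 2) and after 7 days (replicates 1 and 4) with Flt3L. The labels name the day 4 cells as common myeloid progenitors, which give rise to granulocytes, monocytes and dendritic cells, among other blood cells. They name the day 7 cells as bone marrow derived dendritic cells, the antigen-presenting cells this culture is used to produce. At both later times all live cells were taken, without a sort for cell type. The design asks where methylation differs along the route from marrow to dendritic cells.

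The reads at listed cytosines came to 10049788 and 7757919 in the day 0 samples, 10242334 and 6736556 in the day 4 samples, and 8690273 and 3641141 in day 7 replicates 1 and 4. Day 7 replicate 4 was the shallowest, with a median of 4 reads per cytosine against 9 to 14 elsewhere, and 18.5% of its reads lay in the 653 deepest cytosines against 5.13% to 6.47% in the others. Median reads per region were 72 and 56 at day 0, 73 and 48 at day 4, and 60 and 23 at day 7.

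Over the 14004 cytosines with at least 10 reads in each sample, the mean level was 24.7% ± 0.490 (SD, n = 2) at day 0, 25.7% ± 0.606 (n = 2) at day 4 and 26.8% ± 0.309 (n = 2) at day 7. The exact permutation p was 0.333 for each of the 3 comparisons, which is the smallest that 2 samples against 2 can give. Over all 640616 cytosines read in each sample, a set chosen after the data were seen, the means were 45.5% ± 1.23, 47.2% ± 1.11 and 48.4% ± 0.639 (SD, n = 2 each), with exact permutation p of 0.333 for day 4 against day 0 and for day 7 against day 0, and 0.667 for day 7 against day 4. As total methylated over total reads at the 14004 cytosines, the levels were 32.8% ± 1.54, 37.7% ± 0.600 and 49.5% ± 8.95 (SD, n = 2 each), with 43.2% and 55.8% in day 7 replicates 1 and 4. This measure weights the deepest cytosines most. Over all listed cytosines, the 653 deepest hold 18.5% of the reads of replicate 4. The share of the deepest among reads at the 14004 cytosines can be larger and was not computed.

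Grouped by their mean over the 6 samples, the 20324 autosomal regions below 5% stood at 0.993% ± 0.137 at day 0, 1.03% ± 0.123 at day 4 and 2.10% ± 0.214 at day 7 (SD, n = 2 each). The level on the mitochondrial sequence was also highest at day 7, at 0.518% ± 0.0400, 0.919% ± 0.361 and 2.02% ± 0.363 on the 3 days. The 9482 regions between 50% and 80% stood at 68.7% ± 2.72, 72.1% ± 2.38 and 72.8% ± 1.88, and the 20005 regions above 80% at 85.5% ± 1.59, 88.1% ± 1.30 and 88.4% ± 0.780. In both of these methylated classes the day 7 samples overlapped the day 4 samples and lay above both day 0 samples, and no test was run on the classes.

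**Figure D1:**
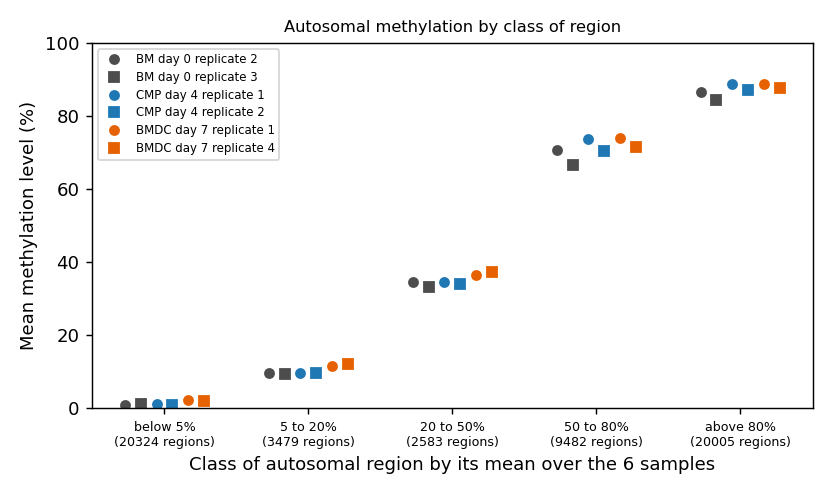
Mean methylation level (percent, vertical axis) of autosomal regions in 5 classes set by the mean over the 6 samples (horizontal axis). Each point is 1 sample; the class below 5% lies near 2% in both day 7 samples and near 1% in the other 4.

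Day 4 against day 0 compares the cells after 4 days of Flt3L with uncultured marrow. A single region of the 56105 tested was called, on chromosome 4 from 10618452 to 10618486 (3 cytosines). It stood at 74.1% and 33.3% in the day 0 samples and at 100% in both day 4 samples, and also at 100% in both day 7 samples, on 15 to 27 reads per sample (adjusted p = 0.01676, edgeR). It falls outside the naming rule because of its low read number and was named after its values were seen. At an unadjusted p below 0.05 there were 3702 regions. Chance alone would put a share of about 0.05 of those tested there. None of the 861 X regions was called. The quasi-likelihood test and limma called 0 regions and Fisher's exact test on pooled reads 358, and without day 0 replicate 3 edgeR called 0. Of the 4 samples compared, leaving out day 0 replicate 2 kept the call of the named region and leaving out any other lost it. Without day 0 replicate 3 its difference was 25.9 points, against 46.3 with all samples (adjusted p = 0.4291), and without day 4 replicate 1 or 2 the adjusted p was 0.2804 or 0.2041. Among 10559 single cytosines edgeR, the quasi-likelihood test and limma called 0, while Fisher's exact test called 5. In edgeR 392 had an unadjusted p below 0.05, fewer than a share of 0.05 of those tested.

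Day 7 against day 0 compares the dendritic cell cultures with uncultured marrow. The main difference lay on the X chromosome, where 205 regions were higher and 1 was lower at day 7 among 861 tested. Of the tested X regions, 23.8% were thus called higher. The day 7 libraries also had more reads per X cytosine relative to autosomal ones, at ratios of 1.00 and 1.04 against 0.643 to 0.683. These X differences therefore need not be methylation gained in culture, a question taken up below. On the autosomes 65 regions were higher and 8 lower among 55146 tested. X regions that rose went from a median of 0.675% at day 0 to 31.1% at day 7, while autosomal regions that rose went from 68.4% to 97.4%. In all, 279 regions were called, 270 higher and 9 lower.

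The X regions that were nearly unmethylated at day 0 took intermediate levels at day 7. Of the X regions, 386 lay below 20% in both day 0 samples. Their mean level was 1.37% ± 0.224 at day 0, 1.47% ± 0.0550 at day 4 and 23.6% ± 0.456 at day 7 (SD, n = 2 each). In 326 of the 386, or 84.5%, both day 7 samples lay above all 4 others. Only 13 stayed below 5% in both day 7 samples. The 23444 autosomal regions chosen in the same way had means of 1.97% ± 0.0860, 2.14% ± 0.105 and 3.43% ± 0.0570. In 5302 of them, or 22.6%, both day 7 samples lay above all 4 others. That share is no chance baseline, since these regions also rose slightly and the choice by low day 0 levels favours this order. The 318 X regions above 80% by their mean over all 6 samples, day 7 included, stood at 86.1% ± 1.44 at day 0, 87.7% ± 1.79 at day 4 and 87.4% ± 0.755 at day 7.

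**Figure D2:**
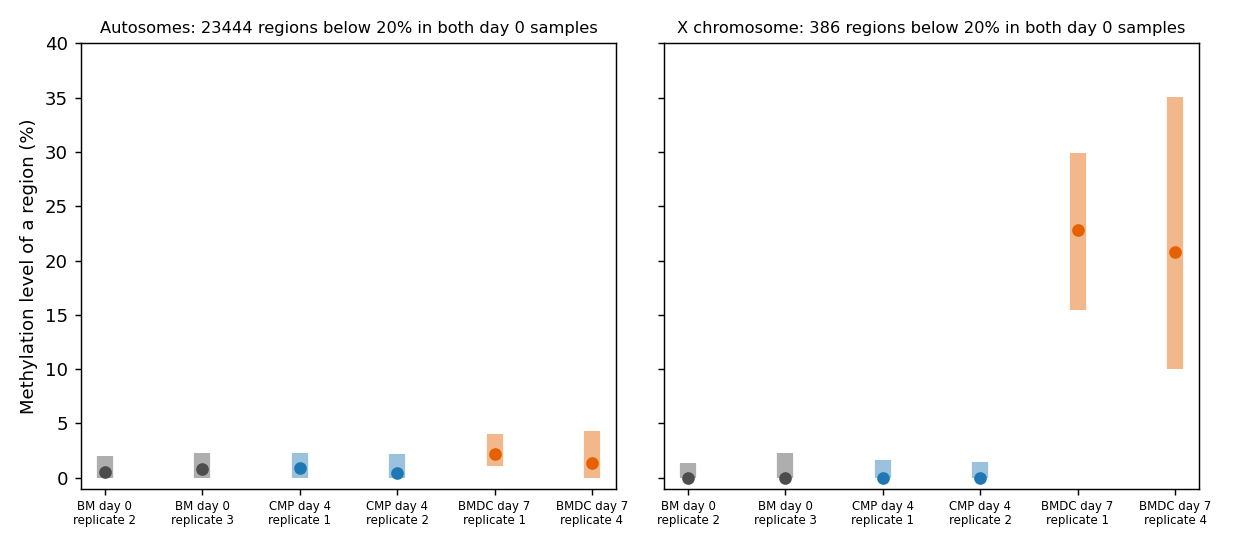
Methylation level (percent, vertical axis) of regions below 20% in both day 0 samples, for autosomes (left) and the X chromosome (right), by sample. Points are medians and bars span the quartiles over regions; X medians are 0% in the 4 day 0 and day 4 samples and 22.8% and 20.8% in the day 7 samples.

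Reads on the X chromosome moved with these levels. Reads per X cytosine divided by reads per autosomal cytosine came to 0.663 and 0.643 in the day 0 samples, 0.683 and 0.677 in the day 4 samples, and 1.00 and 1.04 in the day 7 samples. All 6 samples carry the label male. Reads at 26 cytosines of unplaced Y sequence, per 1000000 autosomal reads, were 68.9 and 71.3 at day 0, 63.4 and 54.2 at day 4, and 36.9 and 35.8 at day 7. The X ratio leaves out the 0.1% deepest cytosines of each sample, while the Y values divide by all autosomal reads. Since the deepest cytosines hold 18.5% of the reads of day 7 replicate 4, its Y value is lowered by this choice.

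**Figure D3:**
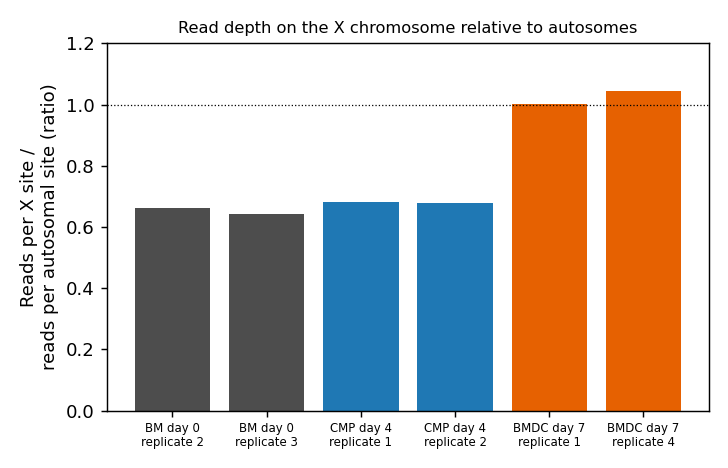
Reads per X cytosine divided by reads per autosomal cytosine (vertical axis, from 0) in each sample (bars). Both day 7 samples, at 1.00 and 1.04, stand above the 4 others, which lie between 0.643 and 0.683.

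Among the 10 largest rises under the naming rule, 8 were X regions. The region from 34138877 to 34138998 (5 cytosines) had 0 methylated reads among 55 and 30 in the day 0 samples, which allow levels of up to 5.45% and 10.0%, and stood at 52.2% ± 14.0 at day 7 (SD, n = 2; adjusted p = 8.071e-08). The longest, from 100517093 to 100517373 (15 cytosines), went from 3.81% ± 0.510 at day 0 and 5.46% ± 0.200 at day 4 to 51.4% ± 0.590 at day 7 (n = 2 each; adjusted p = 5.569e-08). The region from 33868454 to 33868479 had 0 methylated reads in all 4 day 0 and day 4 samples, which allow up to 12.5% in the shallowest, and 40.6% and 45.8% at day 7. The other X regions of the rule, starting at 99445906, 93152167, 13039099, 138158827 and 58148285, reached means of 41.2% to 49.4% at day 7 from 0% to 2.23% at day 0. Day 7 replicates 1 and 4 stood apart at the region starting at 93152167 (29.1% and 61.5%) and at that starting at 13039099 (25.4% and 65.0%), where the differences without replicate 4 were 29.1 and 24.7 points. All 8 passed in both edgeR tests and stayed called with each sample left out.

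The autosomal rises mostly started at intermediate levels and ended near full methylation. Of the 65, 55 lay between 20% and 80% at day 0, 10 lay below 20%, 50 ended above 90% and 21 ended at 100% in both day 7 samples. Since a call needs a rise of at least 20 points, no rise could start above 80%. With the adjustment limited to autosomes 18 rises stayed, and their levels were not grouped. Of the 30 autosomal falls from day 4 to day 7, 11 stood at 100% in both day 4 samples. Where the test can call regions may thus shape the pattern, which was not tested. A region on chromosome 10 from 125222597 to 125222651 went from 45.02% ± 7.89 to 90.6% ± 13.3 (n = 2 each; adjusted p = 0.003487), with 63.6% ± 9.68 at day 4. On chromosome 1, the region from 174206245 to 174206400 went from 59.4% ± 7.61 to 93.4% ± 0.770 (adjusted p = 0.01406), with 79.6% ± 1.18 at day 4. That call was lost with autosomes fitted alone (adjusted p = 0.07092), in the quasi-likelihood test (0.1021) and with any of the 4 samples compared left out (0.06901 to 0.1934).

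Some autosomal rises started low. A region of 16 cytosines on chromosome 11, from 108873012 to 108873270, stood at 19.1% ± 4.23 at day 0, 36.0% ± 8.58 at day 4 and 55.0% ± 12.0 at day 7 (n = 2 each; adjusted p = 0.004156), on 101 to 732 reads per sample. On chromosome 6, the region from 3151209 to 3151245 went from 6.52% ± 0.980 to 40.1% ± 6.37 (adjusted p = 1.077e-05, edgeR). Its reads numbered 1813 to 2620 in the day 0 and day 4 samples, where the median region held 48 to 73. In the day 7 samples they numbered 65 and 132. With such unlike depth the levels may not come from the same DNA and may not be comparable. A further region on chromosome 11, from 5906305 to 5906465, was at 0% in both day 0 samples, whose 126 and 84 reads allow up to 2.38% and 3.57%. It stood at 9.90% and 72.0% in day 7 replicates 1 and 4, so the rise (adjusted p = 9.478e-08) differed widely in size between the replicates.

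Under the rule 2 regions fell. On chromosome 8, the region from 74743809 to 74743941 (7 cytosines) went from 25.3% ± 4.66 at day 0 to 1.47% ± 2.08 at day 7 (n = 2 each; adjusted p = 0.003637), with 16.1% ± 5.48 at day 4. On chromosome 2, the region from 111023467 to 111023490 went from 100% in both day 0 samples to 73.2% ± 3.31 (adjusted p = 0.001424, edgeR). In what follows, the chromosome 6 region carries the limit of its unlike depth given above. Of the 12 named autosomal regions of this comparison, only the region on chromosome 6 stayed called with each sample left out. The chromosome 10 and chromosome 8 regions each lost the call without day 0 replicate 3, the former also without day 7 replicate 4 and the latter without day 7 replicate 1. The chromosome 2 region lost it without either day 0 sample, the longer chromosome 11 region without day 0 replicate 2 or day 7 replicate 1, and the other chromosome 11 region without day 7 replicate 4.

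**Figure D4:**
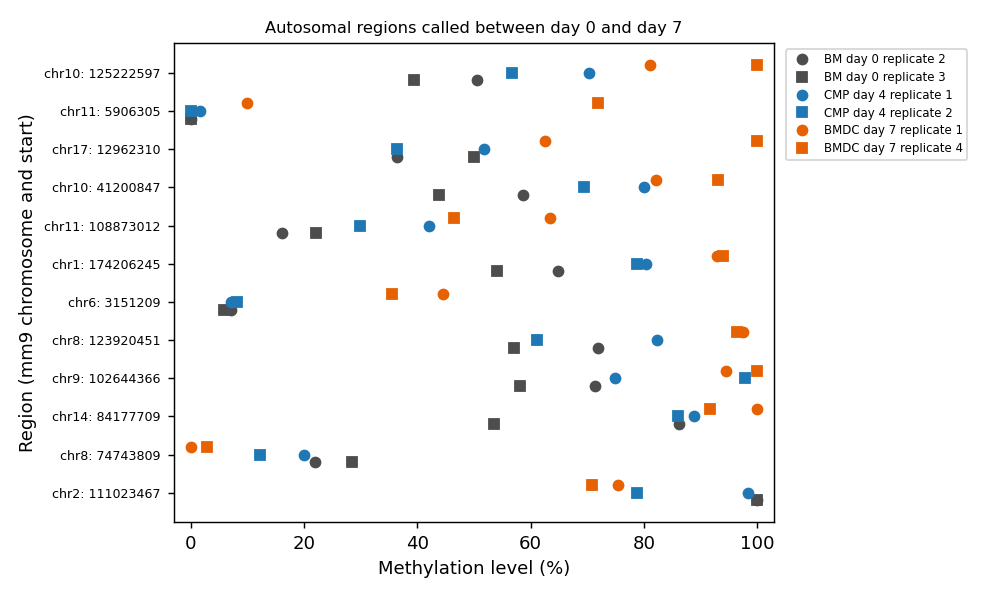
Methylation level (percent, horizontal axis) of the named autosomal regions that differed between day 0 and day 7 (vertical axis, mm9 chromosome and start). Each point is 1 sample; 10 regions lie higher and 2, on chromosomes 8 and 2, lie lower in both day 7 samples than in both day 0 samples.

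Counts on both kinds of chromosome depended on the setting. With autosomes fitted and adjusted alone 23 regions were called, 21 higher and 2 lower, with the adjustment alone limited to autosomes 20 were called, 18 higher and 2 lower, the quasi-likelihood test called 13 on autosomes and limma 0, and without day 0 replicate 3 the count was 28. Without day 7 replicate 1, which leaves the shallow library alone in its group, 49 autosomal regions were higher and 43 lower, and 10 of the 65 rises and 4 of the 8 falls were among them. Without day 0 replicate 2 the count on all chromosomes was 176 and that on the X chromosome 119. Among 10559 single cytosines 11 were called, with 800 at an unadjusted p below 0.05, where chance alone would put a share of about 0.05.

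Day 4 samples do not enter the difference between day 0 and day 7, so their place along it can be read apart. Over all 279 regions, the median share of the change present at day 4 was 0% in both day 4 samples, and it was also 0% over the 205 X regions that rose. Over the 65 autosomal rises the medians were 52.0% and 49.9% in day 4 replicates 1 and 2, and over the 8 autosomal falls 24.0% and 0%. Regions called because their day 0 and day 7 levels lay apart by chance would also place day 4 samples in between, so this share is a description with no test.

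Day 7 against day 4 compares the later with the earlier stage of the culture. Here too the X chromosome held most differences, with 196 regions higher and 1 lower at day 7 among 861 tested. On the autosomes 26 regions were higher and 30 lower among 55146. In all, 253 regions were called, 222 higher and 31 lower. X regions that rose went from a median of 0.415% at day 4 to 31.2% at day 7, beside the X read ratios of 1.00 and 1.04 given above. For the same reason these X differences need not be methylation gained between day 4 and day 7.

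Most autosomal regions that fell, 27 of 30, stood above 80% at day 4, and the other 3 between 20% and 80%. Of the 26 that rose, 18 stood between 20% and 80% at day 4 and 8 below 20%. The minimum difference for a call allows no rise from above 80% and no fall from below 20%. The 30 falls had medians of 98.7% at day 4 and 69.2% at day 7, with 88.0% at day 0, and in 22 of them both day 0 samples lay below both day 4 samples. The 26 rises had medians of 55.4% at day 4 and 93.2% at day 7, with 73.1% at day 0, and in 12 of them both day 0 samples lay above both day 4 samples. Regions selected for an extreme day 4 level tend by selection to show day 0 levels nearer the middle.

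The largest named rise was on chromosome 15 from 73493022 to 73493161 (5 cytosines), which stood at 59.3% ± 2.5 at day 0, 27.5% ± 7.08 at day 4 and 80.3% ± 4.81 at day 7 (n = 2 each; adjusted p = 0.0003067). On chromosome 9, the region from 118937966 to 118938018 had the same order, with 53.9% ± 3.20, 29.4% ± 9.80 and 72.7% ± 12.4 (adjusted p = 0.004259). Of the 10 largest rises, 7 were X regions, led by the region from 34138877 to 34138998 (adjusted p = 2.586e-08, edgeR). The chromosome 6 region starting at 3151209, an autosomal rise, had 2466 and 1813 reads at day 4 but 65 and 132 at day 7. Its levels may therefore not be comparable. Among the 10 named falls, all autosomal, the region on chromosome 10 from 128113609 to 128113645 went from 99.1% ± 1.26 to 76.1% ± 0.0900 (adjusted p = 0.001652) and was the only 1 that also passed the quasi-likelihood test. The largest fall, on chromosome 17 from 88145604 to 88145743, went from 73.5% and 36.2% in the day 4 samples to 18.3% and 17.8% (adjusted p = 0.01728). Without day 4 replicate 1 it fell by 18.2 points (adjusted p = 0.542), and the call was also lost without either day 7 sample, with autosomes fitted alone (0.08383) and in the quasi-likelihood test (0.09988). Of the 20 named autosomal regions of this comparison, the region on chromosome 15 starting at 73493022 and that on chromosome 6 starting at 3151209 stayed called with each sample left out. The chromosome 9 and chromosome 10 regions lost the call without day 4 replicate 2 or day 7 replicate 1.

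The balance of autosomal rises and falls depended on the setting. With autosomes fitted alone 7 regions were higher and 3 lower, the quasi-likelihood test gave 6 and 3, and limma called 0. With no minimum difference 100 were higher and 39 lower. Without day 4 replicate 1 there were 33 and 5, without day 4 replicate 2 there were 10 and 13, and without day 7 replicate 1 there were 57 and 107. Without day 4 replicate 1 the count on all chromosomes was 152 and that on the X chromosome 114. Among 10559 single cytosines 13 were called, with 658 at an unadjusted p below 0.05, where chance alone would put a share of about 0.05.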

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

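The tests of low X and autosomal regions, X reads, mitochondrial level and adjustment over autosomes were chosen after the results were seen, while the fits of autosomes alone and without a sample were planned. Relative to autosomes, both day 7 libraries had more reads on the X chromosome than the day 0 and day 4 libraries. They had 1.003 and 1.043 reads per X cytosine for each read per autosomal cytosine, a measure outside the methylation comparisons. The same libraries had the highest levels on the mitochondrial sequence, at 2.275% (Wilson interval 1.75% to 2.96%, 2374 reads) and 1.762% (1.49% to 2.08%, 7603 reads), against 0.547% and 0.490% at day 0 and 1.17% and 0.664% at day 4. Mammalian mitochondrial DNA is often used as a sequence with little methylation, so its level bounds the unconverted share where nuclear DNA converts alike.

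X regions that were low at day 0 rose by a median of 21.8 points to day 7, and incomplete bisulfite conversion would raise autosomal regions of equally low level as much, but their median rise was 1.083 points. A gain of methylation on the X chromosome of male cells would leave X reads as in the other libraries, but the lower day 7 ratio was 1.469 times the highest of the others. Cells with 2 X chromosomes, of which 1 is inactive and methylated at otherwise unmethylated regions, are a candidate explanation drawn from these X reads and levels, which are therefore no test of it. A further check took 187 X regions above 80% in both day 0 samples, outside the pattern but part of the same X reads. There the lower day 7 ratio was 1.244 times the highest of the others (1.04 and 1.23 against 0.782 to 0.836). That lies just above a limit of 1.2, which was also set after the results were seen. The relative rise was smaller than at X regions below 20% (0.877 and 0.870 against 0.541 to 0.564). Reads on unplaced Y sequence were lower at day 7 but not near 0, at 36.9 and 35.8 per 1000000 autosomal reads against 54.2 to 71.3. At day 0 its 26 cytosines held 674 and 539 reads, while an autosomal cytosine held 14.7 and 11.4 on average. Per cytosine the Y sequence was thus deeper than autosomes, so it may not be single-copy or specific to the Y chromosome. A value above 0 therefore does not show that a Y chromosome was present. Whether all or part of the cells would have 2 X chromosomes stays open. So does the explanation itself, which goes against the sex in the labels and was found in the same data.

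Autosomal rises outnumbered falls between day 0 and day 7, 65 to 8, or 21 to 2 with autosomes fitted alone (exact binomial p = 6.6e-05, which treats regions as independent although they share samples). By the upper bound of the mitochondrial level, unconverted cytosines could add about 2.956 points, if nuclear DNA converted alike. That is below the 20 points each call needs. A small general rise could still make rises cross 20 points more often than falls, so this bound does not decide the excess. Without day 7 replicate 1 there were 49 rises and 43 falls, and without replicate 4 there were 65 and 8, but these are largely other regions: 10 and 24 of the 65 rises were among them. Since the first setting leaves the shallowest library alone in its group, whether the excess rests on replicate 1 stays open. A change in the mix of cell types between marrow and culture cannot be told apart from a change within cells, because 0 regions could be assigned to a cell type. The X reads also leave open whether the day 7 cells came from animals of the labelled sex. A difference between donor animals can therefore not be told apart from time in culture on the autosomes either.

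The number of autosomal calls between day 0 and day 7 depended on the X chromosome. With all chromosomes adjusted together 73 autosomal regions were called. With the same p-values adjusted over autosomes alone 20 were called, and with autosomes both fitted and adjusted alone 23. The larger number is likely a product of the shared adjustment, which X regions with very small p-values relax.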

How the results depend on the processing

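Chosen after the data were seen were regions built only from cytosines with 10 reads in each sample, cytosines with 5 reads or 1 read in each sample, separate counts and adjustment for autosomes, and, for mean levels, autosomes alone and leaving out a sample. The cause of a change was not tested unless the setting itself shows it. For day 4 against day 0 (1 called region, autosomal), no minimum difference gave 2, a minimum of 10 points 2, gaps of 200 bp 2, Fisher's exact test 358 (351 on autosomes), and the quasi-likelihood test, limma, 20 reads per sample, at least 5 cytosines per region, and regions only from cytosines with 10 reads in each sample gave 0; with samples left out the count was 0 to 3, and without day 4 replicate 1 the 1 call was a fall. For day 7 against day 4 (253 regions, 56 autosomal), no minimum difference gave 409 (139), the quasi-likelihood test 166 (9), limma 63 (0), Fisher's exact test 583 (354), regions only from cytosines with 10 reads in each sample 2 (1), autosomes alone 10, adjustment over autosomes 10, at least 5 cytosines 36 on autosomes, and samples left out 152 to 345 (23 to 164). For day 7 against day 0 (279 regions, 73 autosomal), no minimum difference gave 470 (196), the quasi-likelihood test 174 (13), limma 47 (0), Fisher's exact test 788 (559), regions only from cytosines with 10 reads in each sample 2 (1), autosomes alone 23, adjustment over autosomes 20, 20 reads per sample 48 on autosomes, and samples left out 176 to 279 (28 to 92). Fisher's test pools reads and so ignores the spread between replicates. When a sample is left out, the lone sample of its group is assumed to vary like the other groups.

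Called cytosines for day 4 against day 0 (0) became 5 by Fisher's exact test, 1 with 5 reads and 2 with 1 read in each sample, and stayed at 0 with samples left out. For day 7 against day 4 (13) the quasi-likelihood test gave 8, limma 3, Fisher's exact test 31, 20 reads 3, leaving out the 0.1% deepest cytosines 1, 1 read 8, and samples left out 3 to 59, the highest without day 7 replicate 1. For day 7 against day 0 (11) no minimum difference gave 18, 10 points 18, the quasi-likelihood test 7, limma 7, Fisher's exact test 37, 20 reads 1, leaving out the deepest cytosines 3, 5 reads 18, and samples left out 5 to 56, the highest again without day 7 replicate 1.

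Mean levels at day 0, day 4 and day 7 depended on which cytosines were averaged: 32.8%, 37.7% and 49.5% as total methylated over total reads, 41.0%, 43.1% and 44.5% with at least 20 reads in each sample (862 cytosines), 45.5%, 47.2% and 48.4% with at least 1 read, and 24.1%, 25.05% and 26.1% on autosomes. The order of the days was the same in these settings. The SD of the read totals was 8.95 at day 7. With a minimum of 30 points, the share of the change present at day 4 over 31 autosomal rises was 50.9% and 51.03% in the day 4 samples. Over all called regions it says little, since most are X regions near 0% at both earlier times.

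Of the named regions for day 7 against day 0, all 8 on the X chromosome and 1 of 12 on other chromosomes stayed called with each sample left out. For day 7 against day 4 these were 6 of 7 and 2 of 20. The chromosome 6 region among those that stayed called had 1813 to 2620 reads at day 0 and day 4 but 65 and 132 at day 7. Its levels may therefore not be comparable. Depth limits mainly day 7 replicate 4, whose median region held 23 reads. No paired analysis was possible because any 2 groups share at most 1 replicate number. Promoter tests, gene-list tests, marker loci and their alternatives were not run, since gene positions on mm9 were not used here.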

Other observations

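On chromosome 17, a pair of named regions 27.1 kb apart were called in opposite directions, in different comparisons, and neither call was firm. The region from 12935111 to 12935233 (7 cytosines) stood at 66.4% and 18.8% in day 0 replicates 2 and 3, at 31.2% and 59.8% in day 4 replicates 1 and 2, and at 0% and 19.1% in day 7 replicates 1 and 4, where 42 reads allow up to 7.14% in replicate 1. It was called lower at day 7 than at day 4 (adjusted p = 0.01085, edgeR), and the call was lost with autosomes fitted alone (adjusted p = 0.06677), in the quasi-likelihood test (0.07769), without day 4 replicate 2 (0.3735) and without day 7 replicate 1 (0.3639), where it still fell by 21.7 and 26.4 points against 36.0 with all samples. The region from 12962310 to 12962343 (5 cytosines) stood at 36.4% and 50% at day 0, 51.8% and 36.4% at day 4, and 62.5% and 100% at day 7, and it was called higher at day 7 than at day 0 (adjusted p = 0.04777). That call was lost with autosomes fitted alone (adjusted p = 0.1129), in the quasi-likelihood test (0.2147), without either day 0 sample (0.363 and 0.09554) and without day 7 replicate 4 (0.5909), where the differences were 31.3, 44.9 and 19.3 points against 38.1 with all samples.

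By class of mean over the 6 samples, 28 of 861 X regions lay between 20% and 50%, with levels of 29.2% ± 3.45 at day 0, 28.0% ± 4.76 at day 4 and 50.01% ± 3.81 at day 7 (SD, n = 2 each). The 134 between 50% and 80% stood at 70.6% ± 3.08, 74.3% ± 4.41 and 73.3% ± 3.02. The 298 X regions with a mean between 5% and 20% stood at 1.47% ± 0.231, 1.56% ± 0.0680 and 27.5% ± 1.59. The 83 below 5% stood at 0.597% ± 0.142, 0.535% ± 0.116 and 8.14% ± 4.04.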
